A study of Mus musculus with 18 samples.

How the data were processed

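RNA from 6 groups of mouse cells was hybridised to arrays, 3 arrays per group. Total RNA input was 13 µg for the MEF arrays and 500 ng for the ES and NP arrays, per the labels' protocols. The MEF values are log2 expression as deposited, with array medians from 7.38 to 7.42. The submitters' processing notes name MAS5, RMA, affy and limma for them, and which of these gave the values is not given in the sources used here. For the ES and NP arrays the authors deposited probe intensities that were not normalized, per the file headers, with a detection p-value per probe and array. A second deposited table of the same arrays holds processed log2 values with a median of 8.14 on every array; the submitters' processing notes name GenomeStudio, lumi 1.10.1 and limma 2.16.4. Its transform and centring are not given in the sources used here. No column of sample values was left unused.

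Gene names came from the platform annotation, updated through gene identifiers to the RefSeq gene table of assembly GRCm38.p6. Of 22690 Affymetrix probe sets, 20393 had 1 gene symbol, 691 had several and 1606 none; 20364 matched the RefSeq table. Of 45281 Illumina probes, 34885 had 1 symbol, 18 several and 10378 none. Probe sets with several genes were left out, except for Tdg, whose 3 probe sets each carry 3 gene names and were read from the fit over all probe sets. Each gene was represented by the probe set with the highest mean. Of 226 changed MEF genes with more than 1 probe set, 180 had the same direction in all of them. Affymetrix levels had no detection filter, so folds of genes near the low end of the scale may be understated.

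ES and NP intensities were background-corrected with the normal-exponential model of limma 3.58.1 in R 4.3.3, using detection p-values and an offset of 16, and quantile normalized. Probes were kept where the detection p was under 0.01 on at least 3 arrays, which left 19285. The written design took 1 probe per gene name. It was not followed for these arrays because names and values did not go together: mean levels by name correlated with those of the MEF arrays at a Spearman rho of 0.05 over 11865 genes. The comparisons were therefore made over all detected probes, without names or gene lists, and the design as written is given as an alternative. For the same reason no overlap of MEF genes with ES or NP genes was computed.

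Groups were compared with limma (lmFit and eBayes), in a 2-group model for MEFs and in a 4-group model of the 12 ES and NP arrays. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Gene lists, 33 in all, were fixed before the data were examined, as were the tests and the alternatives named as planned. Lists with at least 5 measured members, 32 in the MEFs, were tested with camera at a preset correlation of 0.01 and adjusted over lists; no list passed with an estimated correlation. Genes named in the text were Tdg, the 6 largest rises and 6 largest falls among changed genes whose arrays did not overlap (skipping clone and model names), up to 4 changed members of each list described, the sex-linked genes, and Pax6, Rarb, Hoxa10, Hoxd13, Sfrp2 and Twist2. Genes named only in the closing section outside this rule were chosen after their values were seen.

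The 12 ES and NP arrays lay on 2 slides, each with all 4 groups, and slide was used as a block and the slides were fitted apart, with 2 residual degrees of freedom each. No 2 arrays held identical values. The alternatives were other normalizations, other filters, blocks for slide and replicate number, other probe rules, a 2-fold limit and leaving out each array. The procedure was tested on simulated data with 200 changed rows. For MEFs, over 12394 genes, 18% of genes changed by 0.5 on the log2 scale were recovered, 92% of those changed by 1 and 100% of those changed by 2, and 7.2% of calls were false. For ES cells, over 19285 probes, the shares were 36%, 94% and 100%, with 6.3% false. For the interaction of genotype and cell type they were 6%, 78% and 100%, with 4.1% false. The simulated values were independent between genes, with the same spread on every array, whereas MEF_het replicate 1 stood apart in the data. The simulated MEF shares therefore do not describe the MEF calls made here.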

Results

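Transcript levels were measured on arrays in 18 samples of mouse cells that carried 1 working copy of Tdg (Tdg+/-) or none (Tdg-/-). Tdg encodes thymine DNA glycosylase, a base excision repair enzyme that also removes oxidised forms of methylcytosine from DNA. The cells were embryonic fibroblasts (MEFs) immortalised with SV40, embryonic stem (ES) cells, and neuronal precursor (NP) cells at day 4 of a differentiation induced with 5 µM retinoic acid. Each of the 6 groups of genotype and cell type held 3 samples. The MEFs were hybridised to Affymetrix arrays and came from 1 clone per genotype, clone 4 for Tdg+/- and clone 9 for Tdg-/-. The ES and NP samples were hybridised to Illumina arrays, on which between 15829 and 18062 of 45281 probes were detected per sample. The number of arrays limits the precision. No label says that the 3 samples of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

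The first question was which transcripts differ between MEFs with and without Tdg. Tdg itself was measured by 3 Affymetrix probe sets, each also annotated to Tdg pseudogenes. In the Tdg-/- MEFs the signal of the probe set that fell most was 6.30-fold lower, at 6.34 ± 0.19 against 8.99 ± 0.22 (log2, SD, n = 3), with an adjusted p of 0.000726. The other probe sets were 4.79-fold lower (adjusted p = 0.00543) and 3.46-fold lower (adjusted p = 0.00351). All 3 Tdg-/- arrays lay below all 3 Tdg+/- arrays for each probe set. Without MEF_KO replicate 3 the 4.79-fold fall had an adjusted p of 0.0524. Which part of Tdg was deleted is not given in the sources used here, so a probe set outside that part would check nothing about the knockout.

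Sox2, a transcription factor of pluripotent and neural stem cells, showed the largest rise in Tdg-/- MEFs. It was 13.4-fold higher, at 8.58 ± 0.09 against 4.83 ± 0.20 (log2, SD, n = 3; adjusted p = 5.67e-05). En2, a homeobox gene of the midbrain and hindbrain, rose 8.07-fold, and Cdh2, which encodes N-cadherin, rose 6.72-fold. Gpm6b, a neural membrane glycoprotein gene, rose 5.70-fold, Csrp2 4.91-fold, and Tnfrsf11b, which encodes osteoprotegerin, 4.25-fold. Sfrp2, a secreted regulator of Wnt signalling, showed the largest fall, from 11.67 ± 0.16 to 6.29 ± 0.12 (log2, SD, n = 3), which is 41.7-fold (adjusted p = 1.32e-05). Gjb2, which encodes connexin 26, fell 8.65-fold, the matricellular genes Smoc2 and Postn fell 7.85-fold and 7.60-fold, the growth factor gene Ptn 6.56-fold, and the keratin gene Krt19 5.27-fold. The adjusted p-values of these other 10 genes lay between 5.42e-05 and 0.00779; Krt19 did not pass without MEF_het replicate 2 (0.0526) or MEF_KO replicate 2 (0.0584). Of the genes followed whatever their result, Twist2, a mesenchymal transcription factor, fell 1.95-fold (adjusted p = 0.00313). Pax6 had a log2 fold change of -0.50 ± 0.23 (SE; adjusted p = 0.250) and Rarb one of -0.02 ± 0.14 (SE; adjusted p = 0.912), neither past the threshold.

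**Figure D1:**
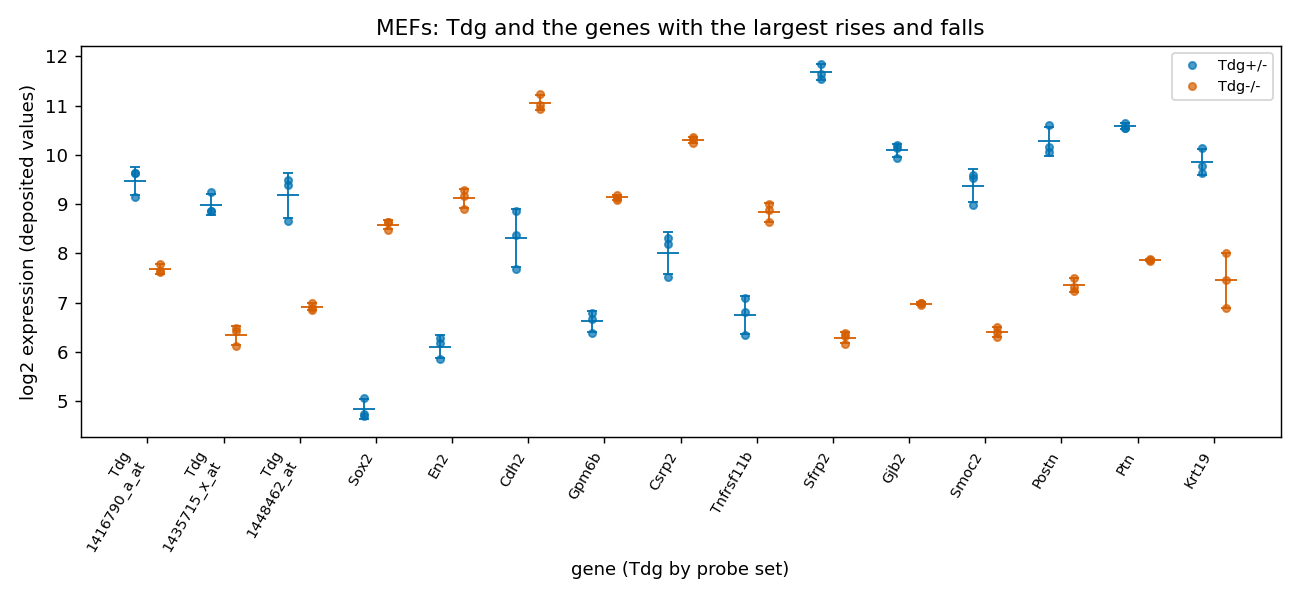
Log2 expression in MEFs (vertical axis, deposited values) of the 3 Tdg probe sets and of the 6 genes with the largest rises and the 6 with the largest falls (horizontal axis). Points are arrays, bars are the mean ± SD of 3 arrays, and the 3 arrays of each genotype do not overlap for any of these items. Sfrp2 fell from 11.67 to 6.29 and Sox2 rose from 4.83 to 8.58.

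Of 31 measured Hox genes, which pattern the body axis and the limbs, 5 fell in Tdg-/- MEFs, none rose and 26 did not pass the test; 13 fell when adjusted over the list alone. The list had a median log2 fold change of -0.48 and a camera adjusted p of 1.18e-08, but did not pass with an estimated correlation (adjusted p = 0.0648). That estimate was 0, under the preset 0.01, so a higher correlation between members does not account for the loss. Hoxd13 fell 3.70-fold (adjusted p = 0.00496), Hoxa10 2.30-fold (adjusted p = 0.00256), Hoxa11 2.27-fold (adjusted p = 0.0259) and Hoxc8 2.00-fold (adjusted p = 0.0155). Hoxa10 was at 5.92 in Tdg+/- and 4.71 in Tdg-/- MEFs (log2), and Hoxc8 at 6.28 and 5.28. These means lie under 6.29, the median of olfactory receptor probe sets on the MEF arrays, so expression of Hoxa10 and Hoxc8 was not established in either genotype. Without MEF_het replicate 1, an array that stood apart from the rest, 19 Hox genes fell and the median was -0.30; without MEF_het replicate 3, 3 fell, and without MEF_het replicate 2 or any 1 of the MEF_KO arrays 2 fell. Hoxa11 and Hoxc8 did not pass when any MEF_KO array or MEF_het replicate 2 was left out, nor Hoxa11 without MEF_het replicate 3, with adjusted p-values up to 0.157 for Hoxa11 and 0.100 for Hoxc8; with a replicate block Hoxc8 had 0.0504.

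**Figure D2:**
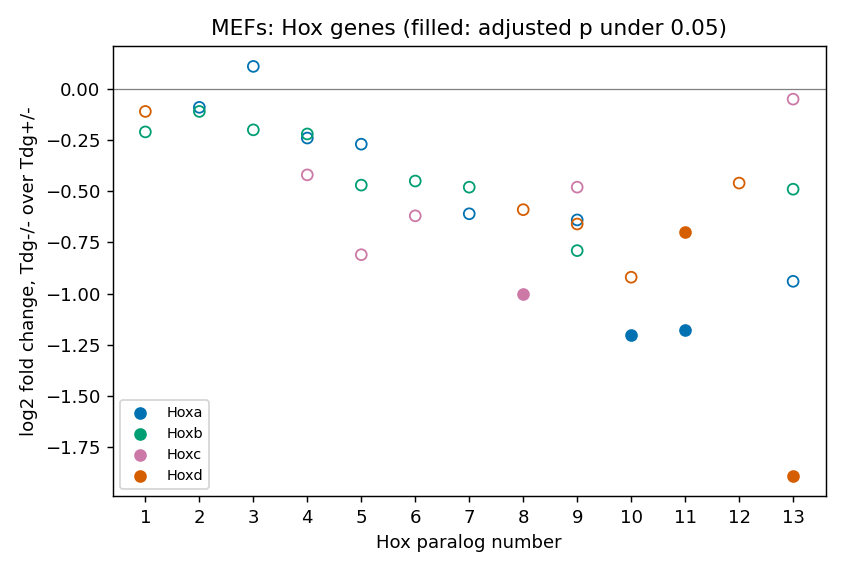
Log2 fold change between Tdg-/- and Tdg+/- MEFs (vertical axis) of the 31 measured Hox genes by paralog number (horizontal axis). Each point is a gene, coloured by cluster and filled where the adjusted p is under 0.05; the filled points run from Hoxd11 at -0.70 to Hoxd13 at -1.89.

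Of 25 measured genes of fibroblasts and feeder cells, 11 fell, 1 rose and 13 did not pass; adjusted over the list alone, 16 fell and 2 rose. The camera adjusted p was 1.48e-07, but the list did not pass with an estimated correlation (adjusted p = 0.316). Beside Postn, the collagen genes Col6a2 and Col3a1 fell 2.44-fold (adjusted p = 0.00256) and 2.21-fold (adjusted p = 0.00503), and the surface marker Thy1 fell 2.26-fold (adjusted p = 0.00233). Among imprinted genes, which are expressed from 1 parental allele, 6 of 27 fell, 1 rose and 20 did not pass; adjusted over the list alone, 8 fell and 3 rose. Igf2 fell 3.26-fold (adjusted p = 0.000393), Plagl1 3.09-fold (adjusted p = 0.000836) and Dlk1 2.85-fold (adjusted p = 0.00127), while Ndn rose 2.17-fold (adjusted p = 0.0387). The camera adjusted p was 0.000856, and the adjusted p was 0.213 with an estimated correlation, which was -0.02 and so under the preset 0.01. Without MEF_het replicates 1, 2 and 3 the fibroblast genes that fell were 18, 7 and 9 and the imprinted ones 11, 3 and 4. Without MEF_KO replicates 1, 2 and 3 they were 6, 6 and 5 and, each time, 3. Leaving out MEF_het replicate 1 took the median log2 fold change from -0.42 to -0.50 for the fibroblast list. For the imprinted list it went from -0.28 to -0.18. Ndn did not pass without MEF_het replicate 2 or any 1 of the MEF_KO arrays (adjusted p up to 0.205). All 8 Ndn probe sets rose, and 2 passed in the fit over all probe sets.

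Interferon response genes fell in 7 of 25 cases, with none higher and 18 not past the test; 12 fell when adjusted over the list alone. Ifit1 fell 3.57-fold (adjusted p = 0.0207), Usp18 3.51-fold (adjusted p = 0.00218), Cxcl10 2.74-fold (adjusted p = 0.0239) and Bst2 2.69-fold (adjusted p = 0.000836). The camera adjusted p was 1.25e-06, and the adjusted p was 0.316 with an estimated correlation. With MEF_het replicate 1 left out, 16 interferon response genes fell and 1 rose; 3 fell without MEF_het replicate 2, and 3, 2 and 2 without MEF_KO replicates 1, 2 and 3. Of 23 genes of glycolysis and hypoxia, 6 rose, 1 fell and 16 did not pass; adjusted over the list alone, 12 rose and 1 fell. The glycolytic genes Pfkl and Aldoa rose 1.71-fold (adjusted p = 0.0281) and 1.70-fold (adjusted p = 0.0148), Bnip3 rose 1.60-fold (adjusted p = 0.0151), and Adm, which encodes adrenomedullin, fell 3.00-fold (adjusted p = 0.00313). The camera adjusted p was 0.000259, and the adjusted p was 0.496 with an estimated correlation. Of the genes of glycolysis and hypoxia 12 rose without MEF_het replicate 1, and none without MEF_het replicate 2 or any 1 of the MEF_KO arrays. Ifit1, Cxcl10, Pfkl, Aldoa and Bnip3 did not pass without MEF_het replicate 2 or any 1 of the MEF_KO arrays, with adjusted p-values up to 0.172 for Pfkl, and Pfkl and Bnip3 had 0.0509 with a replicate block.

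Some genes of the neural progenitor, mesoderm, trophoblast and endoderm lists changed in the MEFs. Of 27 neural progenitor genes, Sox11 rose 4.06-fold (adjusted p = 0.0177), Nes 1.90-fold (adjusted p = 0.00504) and Zic1 1.64-fold (adjusted p = 0.0256), and 24 did not pass; only 1 of the 3 Nes probe sets had that direction. Zic1 was at 5.51 in Tdg+/- and 6.22 in Tdg-/- MEFs (log2), under the olfactory receptor median of 6.29 in both, so its expression was not established. Adjusted over the list alone, 5 neural progenitor genes rose and 1 fell, and the camera adjusted p was 0.735. Of 17 mesoderm genes, Eomes fell 1.98-fold, Bmp4 1.95-fold and Kdr 1.50-fold, and 14 did not pass, as when adjusted over the list alone. The mesoderm list had a camera adjusted p of 0.000961, and an adjusted p of 0.316 with an estimated correlation. Of 11 trophoblast genes, Gata3 fell 3.12-fold and Cdh3 1.47-fold, also the 2 that fell when adjusted over the list alone. The trophoblast list had a camera adjusted p of 0.00268, and an adjusted p of 0.316 with an estimated correlation. Of 21 endoderm genes, Foxa2 rose 2.77-fold and Lamb1 2.18-fold, and Apoe fell 1.51-fold, with the same 2 to 1 split when adjusted over the list alone. The camera adjusted p of the endoderm list was 0.308. All 3 Lamb1 probe sets rose, but none passed in the fit over all probe sets. Sox11, Zic1, Eomes, Kdr, Cdh3, Lamb1 and Apoe did not pass without MEF_het replicate 2 or any 1 of the MEF_KO arrays (adjusted p up to 0.212, for Lamb1), nor Bmp4 without any 1 of the MEF_KO arrays (up to 0.0664); Eomes and Kdr did not pass without MEF_het replicate 3 either. With a replicate block Zic1, Eomes, Kdr, Cdh3 and Apoe did not pass (0.0509 to 0.0764). More passed without MEF_het replicate 1: 7 neural progenitor genes rose and 2 fell, 5 mesoderm genes fell, and 3 endoderm genes rose and 4 fell. Over all genes the count then rose as well, from 475 to 2722. The list medians (log2) shrank from -0.29 to -0.19 for mesoderm and from -0.22 to -0.12 for trophoblast. For endoderm the median went from -0.22 to -0.07 and for neural progenitor genes from -0.12 to -0.06. The camera adjusted p was then 0.00421 for the mesoderm list and 0.0341 for the trophoblast list.

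Patterning and signalling genes moved both ways. Of 35 limb and mesenchyme patterning factors, 3 rose, 3 fell and 29 did not pass; adjusted over the list alone, 5 rose and 6 fell. Osr2 fell 2.80-fold and Tbx15 2.71-fold, while En1 rose 2.15-fold, and the camera adjusted p was 0.0753. Of 18 retinoic acid response genes, Crabp2, which encodes a retinoic acid binding protein, fell 3.22-fold, Nr2f1 rose 1.89-fold and Tgm2 1.39-fold; 2 rose and 3 fell when adjusted over the list alone, and the camera adjusted p was 0.173. Of 30 Wnt pathway genes, Sfrp2 and Fzd4 fell, Wnt4 rose 2.45-fold and Dkk3 2.13-fold, and 26 did not pass; 2 rose and 6 fell when adjusted over the list alone. The Wnt list had a camera adjusted p of 0.0132 downward, and an adjusted p of 0.316 with an estimated correlation. Nr2f1, Tgm2 and Fzd4 did not pass without MEF_het replicate 2 or any 1 of the MEF_KO arrays (adjusted p up to 0.235, for Fzd4), nor Nr2f1 and Tgm2 without MEF_het replicate 3, nor Dkk3 without any 1 of the MEF_KO arrays (up to 0.0709). With a replicate block Nr2f1, Tgm2 and Fzd4 did not pass (0.0547 to 0.0931), nor did Nr2f1 (0.0562) and Tgm2 (0.209) with quantile normalization. Of the 6 Tgm2 probe sets 5 rose, and 1 passed in the fit over all probe sets. The 2 Fzd4 probe sets fell, and none passed in that fit. Without MEF_het replicate 1, 5 patterning factors rose and 12 fell, 3 retinoic acid response genes rose and 4 fell, and 2 Wnt pathway genes rose and 7 fell. The medians (log2) of these lists then went from -0.24 to -0.08, from -0.09 to -0.13 and from -0.21 to -0.12. The Wnt list had a camera adjusted p of 0.0280 without that array. With any other array left out 2 patterning factors rose.

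In 5 further lists the camera test passed with at most 1 single member past it. Polycomb genes (median log2 fold change 0.26, adjusted p = 0.00212) and DNA replication genes (0.21, adjusted p = 0.000223) had raised medians, and cholesterol synthesis genes too (0.18, adjusted p = 0.00831), while endothelial genes (-0.23, adjusted p = 0.0101) and germline genes (-0.11, adjusted p = 0.0419) had lowered ones. None of the 5 passed with an estimated correlation, where the adjusted p was 0.316 for the polycomb list, 0.496 for the endothelial list and 0.591 for the others. Without MEF_het replicate 1 the medians shrank to 0.153, 0.121, 0.088, -0.089 and -0.067 in that order, and the cholesterol, endothelial and germline lists had adjusted p-values of 0.0742, 0.0626 and 0.329; without MEF_KO replicate 2 the germline list had 0.0552. With fry in place of camera only the polycomb list passed (adjusted p = 0.0264). Ebp, 1.59-fold higher, was the only cholesterol synthesis member past the threshold and Kdr the only endothelial one, with none in the other lists. Adjusted over each list alone, 5 cholesterol synthesis genes were higher and the other lists were unchanged. Direction went with signal level here. The median levels (log2) were 8.71, 9.41 and 9.12 for the raised lists and 6.31 and 5.52 for the lowered ones. The fibroblast list, at 10.95, nevertheless fell. Over all genes the median log2 fold change was -0.019, and 0.128 with the probe sets of below-median mean level left out. Whether level accounts for these shifts was not tested. With MEF_het replicate 1 left out, 5 polycomb, 8 DNA replication and 5 cholesterol synthesis genes rose, 1 cholesterol synthesis and 2 endothelial genes fell, and 1 germline gene moved each way; without MEF_het replicate 3, 2 cholesterol synthesis genes rose. Ebp did not pass without MEF_het replicate 2 or any 1 of the MEF_KO arrays (up to 0.161), with a replicate block (0.0645) or with quantile normalization (0.0711), and Kdr is given above. Of the 4 measured sex-linked genes, none passed; Xist was at 6.80 ± 0.20 in Tdg-/- and 7.05 ± 0.32 in Tdg+/- MEFs (log2, SD, n = 3).

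In all, 475 of 12394 genes differed between the MEF genotypes, 312 higher and 163 lower without Tdg, and 147 of them changed at least 2-fold. The count was 2722 without MEF_het replicate 1, 129 without MEF_het replicate 2, and 116, 111 and 95 without MEF_KO replicates 1, 2 and 3. It was 237 with a replicate block. The share of rises was 65.7%, and 55.6% with quantile normalization, 63.3% with the replicate block and 73.7% with the probe sets of below-median mean level left out. It was 64.1%, 53.5% and 71.4% without MEF_het replicates 1, 2 and 3, and 54.3%, 52.3% and 53.7% without MEF_KO replicates 1, 2 and 3. After a loess correction of MEF_het replicate 1 against signal level, chosen after the data were seen, 507 genes rose and 287 fell. With array weights, whose estimate stopped before convergence, 3952 rose and 4986 fell. MEF_het replicate 1 correlated at 0.953 and 0.962 with the other arrays of its group, whereas the correlation between those was 0.997.

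The next question was whether transcripts differ between the genotypes in ES cells and in NP cells. In ES cells 638 of 19285 detected probes differed, 256 higher and 382 lower in Tdg-/- cells, with changes from a log2 fall of -2.40 to a rise of 1.53. In NP cells 3308 probes differed, 1588 higher and 1720 lower, from -2.42 to 2.02. At least 2-fold changes were seen for 33 probes that rose and 22 that fell in ES cells, and for 252 and 268 in NP cells. No gene is named for either cell type, and Tdg was not checked in them, because the probe identifiers of the Illumina tables did not go with their values. Probes named for ribosomal proteins were detected in 36% of cases and probes named for olfactory receptors in 38.4%, while on the MEF arrays the median levels of these families were 12.15 and 6.29 (log2). Neither of the 2 probes named Pou5f1, a gene active in ES cells, was detected on any ES array.

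In ES cells the count depended on single arrays, and the split between higher and lower probes on the scaling. The count was 256 without ES_het replicate 1, 242 without ES_het replicate 3, 351 without ES_KO replicate 1 and 321 without ES_KO replicate 2. With median scaling 87 ES probes were higher and 564 lower, and in NP cells 776 were higher and 1633 lower; the median log2 fold changes of all probes were then -0.148 and -0.076. With the slide as a block, 562 ES probes and 3129 NP probes differed. Within a slide each comparison of genotypes sets 1 array against 2, with 2 residual degrees of freedom and the lone array assumed to vary like the others, so a count of 0 there says nothing about the effect. No ES probe passed limma's test within slide 1 or slide 2 (2112 and 1781 at an unadjusted p under 0.05), and 188 and 702 NP probes did. The log2 fold changes of slides 1 and 2 correlated at 0.41 in ES cells and 0.66 in NP cells across all probes.

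The genotype effect differed between NP and ES cells for 2015 probes, tested as the interaction of genotype and cell type, 1051 with a higher and 964 with a lower effect in NP cells. No label gives a clone or line for the ES and NP samples. Tdg and other differences between the cells of each genotype therefore cannot be told apart here either. In both cell types, 132 probes changed in the same direction, 54 up and 78 down, against 21.1 and 34.1 for independent lists, and 108 changed in opposite directions, against 54.3 for independent lists. Across all 19285 probes the log2 fold changes of ES and NP cells correlated with a Pearson r of 0.08 and a Spearman rho of 0.11; probes are not independent replicates. With median scaling 1226 probes differed in effect, 707 higher and 519 lower in NP cells. With the slide as a block 1766 did, and none passed within slide 1 or slide 2 (2685 and 2722 at an unadjusted p under 0.05 with limma), where 2 of the 4 groups hold 1 array each and 2 residual degrees of freedom are left. The interaction estimates of the 2 slides correlated at 0.55 across all probes. The ES and NP comparisons share no arrays, but both take the error of each probe from the same model. A probe with a low error is more readily called in both, so the lists are not independent. The counts exceeded those for independent lists in the same and in opposite directions. The excess therefore does not by itself show a shared genotype effect. The 132 shared probes were 70 without ES_het replicate 1, 64 without ES_het replicate 3 and 86 without ES_KO replicate 1.

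The last question was how ES cells and NP cells differ within each genotype. In Tdg+/- cells 13405 of the 19285 probes differed between NP and ES cells, 6686 higher and 6719 lower in NP cells. In Tdg-/- cells 13636 differed, 6859 higher and 6777 lower. Of these, 11708 changed in the same direction in both genotypes, 87.3% of those called in Tdg+/- cells, and 108 in opposite directions. The log2 fold changes of the 2 genotypes correlated with a Pearson r of 0.943 and a Spearman rho of 0.93 across probes. NP and ES arrays lay apart on the leading principal component, and NP arrays of the 2 genotypes lay apart on the next. ES arrays of the 2 genotypes lay apart on the one after that, at 12.28 to 18.38 in Tdg+/- and -24.91 to -9.80 in Tdg-/- cells. With the slide as a block 13441 probes differed in Tdg+/- and 13525 in Tdg-/- cells. Within a slide each of these comparisons sets 1 array against 2. The log2 fold changes of slides 1 and 2 correlated at 0.97 in Tdg+/- and 0.96 in Tdg-/- cells across all probes.

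**Figure D3:**
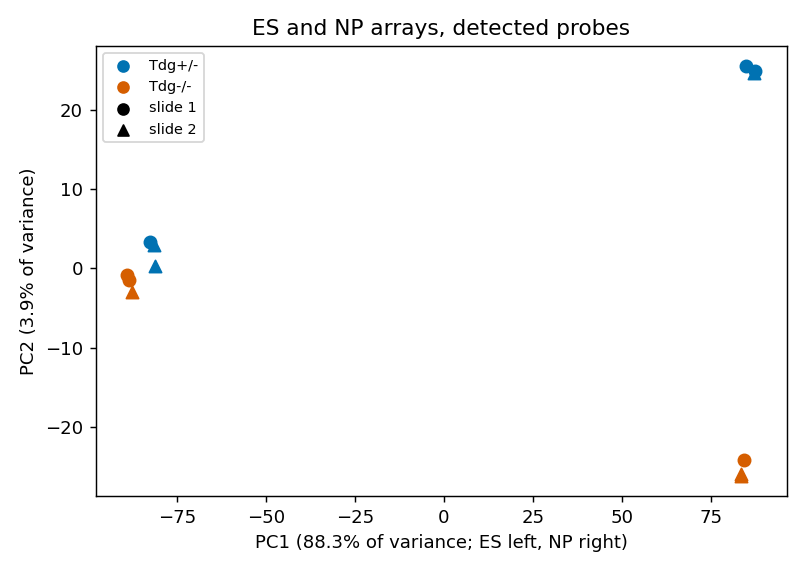
Principal components of the 12 ES and NP arrays over 19285 detected probes; the horizontal axis holds 88.3% and the vertical axis 3.9% of the variance. Each point is an array, coloured by genotype and shaped by slide; ES arrays lie between -89.0 and -81.3 and NP arrays between 83.5 and 87.4 on the horizontal axis.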

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

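The tests of chromosomes, of other cell types and of regrouped arrays were set before their results were seen; those of MEF_het replicate 1 alone, of clones, of signal scale and of probe identifiers were chosen after the patterns were seen.

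The genotype effect differed between NP and ES cells for 2015 probes, in the test of the interaction itself. Of 100 regroupings of the arrays within cell types, drawn from 200, 2 gave as many calls, the real one included. They also break up the genotype effect within each cell type, so their share does not test the interaction, and chance is not excluded by it. The highest other count was 2536, from the regrouping that keeps the genotype groups and exchanges their names in 1 cell type, which adds the 2 genotype effects instead of subtracting them; the next were 1065 to 1259, from the 6 that keep the NP groups and mix the ES arrays. For the other comparisons 3 arrays against 3 make 10 splits, too few for a share under 0.05. In each only 1 split, the real one, reached its count. The real and the highest other counts were 475 and 0 for MEFs, 638 and 1 for ES cells, 3308 and 1 for NP cells, 13405 and 0 for differentiation in Tdg+/- cells, and 13636 and 0 in Tdg-/- cells. Every other split puts arrays of both groups on each side, so a difference between the groups adds to the spread within the sides. The low counts of those splits therefore lend no support to the real ones.

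The 475 genes that differed between MEF genotypes could reflect differences between the clones other than Tdg, since there was 1 clone per genotype. Whole-chromosome copy number as the main cause is argued against: after each chromosome's median log2 fold change was subtracted, 92.6% of the calls remained in the same direction, and the medians of the 20 chromosomes with at least 50 genes lay between -0.07 and 0.09. Without MEF_het replicate 1, 100% of the calls were made in the same direction, so they do not depend on that array. This could not test that array as the cause. A gene shifted by it alone would have a wide spread in its group and would hardly be called. Tdg and any other difference between the 2 clones cannot be told apart with 1 clone per genotype.

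MEF_het replicate 1 stood apart from the other MEF arrays. Its deviation from the mean of the other 2 arrays of its group fell with signal level (Spearman rho -0.48 across probe sets). A change of scale with signal as the whole cause is argued against, because after a loess correction its lower correlation with those arrays was still 0.964, from 0.953 before (the correction took the MEF count from 475 to 794), and level accounted for 22.1% of the variance of the deviation. RNA of another cell type is argued against as far as 10 marker lists go: the highest, smooth muscle and contractile genes, reached the percentile 97 among 10000 random lists matched on level, under the limit set beforehand. RNA quality and hybridisation were not tested, and no biological explanation was tested.

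In the Illumina tables, probe names and values did not go together. Arrays that measured only noise are argued against, since the lowest correlation of replicate arrays was 0.989. An annotation that scatters names at random over the identifiers is argued against by the order of the table, in which 49.6% of 9172 probe pairs of 1 name lie in neighbouring rows. Names displaced in blocks would keep such pairs together, so they cannot be told from displaced values this way. Identifiers attached to the wrong rows of values are a candidate explanation: detected probes of 1 name over 1000 rows apart correlated with a median of -0.024, against 0.016 for random pairs, while neighbouring rows correlated at 0.51 with the same name and 0.52 with different names. No biological explanation was tested.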

How the results depend on the processing

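The array weights, the separate slides, and for gene lists median scaling and leaving out arrays, were chosen after seeing the data; so were the blocks and left-out arrays for shared effects. The cause of a change was not tested except where fewer arrays or probes make it plain. In MEFs, 475 genes became 237 with a replicate block, 147 with a 2-fold limit and 8938 with array weights, whose estimate stopped before convergence and gave MEF_het replicate 2 a weight of 121; without single arrays the range was 95 to 2722. Quantile normalization gave 335 up and 268 down against 312 and 163. All 13 lists lost their call with an estimated correlation, leaving 0 (4 at an unadjusted p under 0.05 with camera), and 10 to 16 passed without single arrays. The estimates for the Hox and imprinted lists were 0 and -0.02, under the preset 0.01. A higher correlation between members therefore does not account for the loss of these calls. In the other called lists the estimate lay between 0.03 (Wnt) and 0.48 (DNA replication). Endothelial, germline and cholesterol lists were lost without MEF_het replicate 1 and with quantile normalization, and they and the DNA replication list with fry. Lists called with fry and not with camera were retinoic acid response (fry adjusted p = 0.00372), limb and mesenchyme patterning factors (0.00890) and smooth muscle and contractile genes (0.0114).

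Same-numbered MEF arrays deviated from their group means with correlations of 0.33, 0.01 and 0.37, and differently numbered ones with -0.395 to 0.15. Same-numbered arrays in the other comparisons gave none over 0.1. No label makes the numbers pairs, so they were not taken as pairs in the main fit. The ES and NP arrays cannot speak to the MEFs, for which a batch shared by number is not excluded. The replicate block left 500 ES and 2961 NP probes, 237 MEF genes as above, and moved no other count by over 1.5 times; it ended the calls of 12 named genes and of the germline list (adjusted p = 0.0530). In MEFs only MEF_het replicate 2 correlated better with another number than with its own (0.15 against 0.01). Not every ES and NP array correlated best with its own number.

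In ES cells 638 probes became 981 in the authors' deposited table, 422 with 1 probe per gene name, 294 with only the 2 groups, 55 with a 2-fold limit, 0 and 0 within slides 1 and 2, where 1 group has a single array, and 242 to 442 without single arrays. In NP cells 3308 became 1949 with 1 probe per name, 520 with the 2-fold limit, 188 and 702 within slides, and 2498 to 2934. Differentiation in Tdg+/- cells gave 7628 with 1 probe per name, 8883 names with any probe past the test, 5757 with the 2-fold limit and 12685 to 12790 without single arrays; in Tdg-/- cells these were 7732, 9026, 5970 and 12837 to 13191. The interaction's 2015 became 1226 with median scaling, 1203 with 1 probe per name, 717 with the 2-fold limit, 0 and 0 within slides, and 1548 to 1896. The 132 shared ES and NP probes became 12 and the 11708 shared differentiation probes 4700 with the 2-fold limit; the 132 ranged from 64 to 141 without single arrays.

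Of 661 values of named genes under alternatives, 547 kept direction and call, 105 lost the call, 5 gained it and 4 turned, all for uncalled genes. Rarb turned to 0.065 with quantile normalization and ranged from -0.151 to 0.08 without single arrays (0.045 without MEF_KO replicate 3), and Uty turned to 0.005 with quantile normalization. A pseudocount was not run for MEFs, whose values are log2.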

Other observations

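Single members of lists not yet described changed in the MEFs, and were chosen after their values were seen. Col2a1, the main collagen of cartilage, was higher in Tdg-/- MEFs by 1.97 on the log2 scale (adjusted p = 0.00127) and was the 1 of 12 cartilage and bone genes past the threshold; adjusted over the list alone, 2 rose and 1 fell, and the camera adjusted p was 0.394. Klf4, a reprogramming factor, was 2.49-fold higher (adjusted p = 0.0213), so that with Sox2 2 of 27 pluripotency genes rose, as when adjusted over the list alone, and the camera adjusted p of that list was 0.0750. Pdgfra, a receptor of mesenchymal and glial progenitors, was 2.35-fold lower (adjusted p = 0.0031), and Cspg4 1.36-fold lower (adjusted p = 0.0434), the 2 of 12 glial genes past the threshold, also when adjusted over the list alone; the camera adjusted p was 0.132. Klf4 did not pass without MEF_het replicate 2 or any 1 of the MEF_KO arrays (adjusted p up to 0.127), and Cspg4 not without any 1 array other than MEF_het replicate 1 (up to 0.245). Without MEF_het replicate 1, 3 cartilage and bone genes rose and 1 fell, and 2 pluripotency and 2 glial genes moved each way. None of the 18 base excision repair genes and none of the 17 genes of DNA methylation and demethylation passed, and their camera adjusted p-values were 0.267 and 0.225; none passed when adjusted over each list alone. In these lists 2 repair and 5 methylation genes rose, and 1 of each fell, without MEF_het replicate 1.

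The other 10 lists were neuron, smooth muscle, skeletal muscle, adipocyte, macrophage, trithorax, p53 target, apoptosis, mitosis and stress response genes. Each had at most 2 members past the threshold and no camera call; adjusted over the list alone, 5 stress response genes rose and 2 fell, and no other list had over 3. Up to 8 rose (stress response) and up to 5 fell (mitosis) without MEF_het replicate 1; without MEF_het replicate 3, 2 apoptosis genes and 1 stress response gene rose, and no neuronal gene passed; without MEF_het replicate 2 or any 1 of the MEF_KO arrays no neuronal and no stress response gene passed.

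The test on Hox genes was chosen after the result was seen. The falls may be larger in posterior paralog groups: across 31 Hox genes, which are not independent replicates, the log2 fold change correlated with the paralog number at a Spearman rho of -0.66 (permutation p = 7e-05) and a Pearson r of -0.63 (permutation p = 7e-05), both two-sided with 100000 permutations. The 13 genes of paralog group 9 and above had a median of -0.70 and the other 18 one of -0.34. Some genes on each side had mean levels (log2) under 6.29, the median of olfactory receptor probe sets on the MEF arrays. Among them were Hoxd10 (5.49), Hoxd12 (5.45) and Hoxb13 (5.35), and on the other side Hoxb1 (5.32) and Hoxd1 (4.91). Expression of such genes was not established, and the trend without them was not tested. The rho was -0.50 without MEF_het replicate 1. Mean level and paralog number correlated at a rho of -0.04. With 1 clone per genotype, a different origin of the 2 clones along the body axis could give the same pattern, and was not tested.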
